A study of Mus musculus with 8 samples.

How the data were processed

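RNA of early-passage mouse embryonic fibroblasts was measured in 8 libraries: WT or mutant at the Dino locus, with vehicle or 0.2 µg/mL doxorubicin for 8 h, n = 2 per group. The labels name both an exome-capture RNA kit and 3' end sequencing, and this was not resolved here. The deposited values are raw counts per gene name, which the authors made by aligning reads to the mouse mm9 genome with Bowtie2 and counting them with HTSeq, per the labels, with no normalization. No information on the annotation, the strand setting or the treatment of reads that match several places was used here, so genes that share reads with near-identical copies or with overlapping or antisense genes are uncertain.

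The table held 30419 gene names, of which 18596 had a count in at least 1 library. UCSC transcript identifiers stood in place of a symbol for 5598 of them and took 11.2% to 15.9% of the counts of a library, and 266 of these were among the genes tested. A spreadsheet had turned 27 symbols into dates, and 2 names were duplicated. Total counts per library ran from 25482805 to 33285171. A count of 0 allows up to 3 counts in a library, or 0.0880 to 0.120 CPM, and this covers counting error only, since reads are not independent molecules. The biological coefficient of variation was 0.0636. Scatter between libraries A and B, as chi-square per degree of freedom over genes, was 6.51 in WT control, 18.8 in WT with doxorubicin, 5.90 in mutant control and 5.71 in mutant with doxorubicin, where duplicates of 1 library would give about 1.

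Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes passed filterByExpr on the 4 groups (minimum count 10, minimum total count 15), which left 12255. TMM factors scaled the libraries, and a quasi-likelihood model with 1 coefficient per group was fitted to all 8 libraries (4 residual degrees of freedom). The comparisons were the response to doxorubicin in WT and in mutant cells, the difference between these responses, mutant against WT without and with doxorubicin, and the average response. Two-sided p-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. The SE of a log2 fold change was its size divided by the square root of the F statistic. The pipeline was tested on simulated data: with WT doxorubicin libraries changed by log2 0.5, 1 and 2, 44.2%, 75.9% and 93.7% of the changed genes were called in the WT response, and 24.7%, 55.2% and 82.5% in the difference. Only 77, 58 and 63 of 11971 genes were changed by these sizes. In the real WT response 7037 genes were called, so the shares for that response may not hold there. The difference called 110 genes in this simulation and 9 in the real data, so its shares may not hold either.

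Gene lists were fixed before the data were examined: p53-activated genes, p53 apoptosis genes, G2/M and mitosis, G1/S and DNA replication, homologous recombination and Fanconi anemia repair, replication-dependent histones, NF-kappaB and inflammatory genes, interferon-stimulated genes, immediate early genes, the ATF4 integrated stress response, endoplasmic reticulum chaperones and unfolded protein response, NRF2 antioxidant genes, cholesterol biosynthesis, extracellular matrix and fibroblast genes, smooth muscle and myofibroblast genes, ribosomal protein genes, mitochondrially encoded genes, markers of endothelial, macrophage and leukocyte, erythroid, skeletal muscle, neural, epithelial, and cartilage and bone cells, Hox and limb or trunk patterning genes, sex-linked genes and genes near Cdkn1a. The lists overlap in part, since the apoptosis list shares genes with the p53-activated list. The list of genes near Cdkn1a holds Cdkn1a itself. Lists with at least 3 tested genes, 25 in number, were tested against all other genes with camera at a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated for each list, and with fry. Members were also adjusted over the list alone.

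The genes named were set by a rule fixed at the same time: Cdkn1a, Mdm2 and Trp53; the 8 largest changes per direction among called genes with a mean of at least 4 CPM whose libraries did not overlap; up to 4 called members of each list, or 2 if none was called; and the sex-linked genes. Some genes that the rule picks are not reported here. Alternatives planned then were edgeR with DESeq2 size factors or upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter, a filter of 5 CPM in 2 libraries, an adjusted p of 0.10, terms for the library letter, only the 4 libraries compared, and leaving out each library. For genotype comparisons, leaving out the genes of chromosomes X and Y was added after seeing the data. The table was made on mm9, and chromosomes and gene order came from a GRCm38 annotation, which matched 11847 of the 12255 names (96.7%).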

Results

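RNA was sequenced in 8 libraries of early-passage mouse embryonic fibroblasts, in 4 groups of n = 2 libraries with the letters A and B. The cells carried the normal Dino locus (WT) or lox sites at Dino on both alleles (mutant), and received vehicle (control) or 0.2 µg/mL doxorubicin, a drug that causes DNA breaks, for 8 h. Dino is a long noncoding RNA gene beside Cdkn1a that p53 activates, and its own level was not analysed here. The total gene counts of libraries A and B were 27245979 and 33285171 for WT control, 27958656 and 31399132 for WT with doxorubicin, 30371446 and 30250652 for mutant control, and 25482805 and 25881067 for mutant with doxorubicin. Of 30419 gene names, 12255 had enough counts to be tested. Along the first principal component, which held 82.3% of the variance, the treated libraries lay apart from the controls, and along the second, with 9.54%, the mutant libraries lay apart from the WT libraries. Nothing in the labels says that the letters stand for separate cultures or embryos, so the p-values may measure technical spread only. Values are counts scaled to library size (CPM) as mean ± SD or log2 fold changes ± SE, each over n = 2 libraries per group.

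The level of sex-linked genes separated the genotypes. Xist, the RNA that coats the inactive X chromosome, was at 0.277 ± 0.0236 CPM in WT control libraries and 233 ± 29.4 CPM in mutant control libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were present in every library, and in mutant control libraries stood at 13.6%, 15.5%, 11.8% and 13.1% of their WT control level. With doxorubicin these shares were 13.0%, 14.8%, 12.9% and 13.9%, and Xist was at 0.304 ± 0.102 CPM in WT and 522 ± 74.5 CPM in mutant libraries. Sex-linked expression thus differed between the genotypes in the same libraries as every gene named in a comparison of the genotypes.

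The first comparison asked how normal cells respond to DNA damage. In WT cells, Mdm2, the ubiquitin ligase that limits p53, rose 8.50-fold, from 136 ± 5.32 to 1158 ± 64.6 CPM (log2 fold change 3.09 ± 0.07). Cdkn1a, which encodes the cell cycle inhibitor p21, rose 5.48-fold, from 12.6 ± 1.76 to 69.3 ± 4.48 CPM (log2 fold change 2.46 ± 0.10). Trp53 itself did not pass the test, with a log2 fold change of -0.21 ± 0.14. Rai2 rose from 0.708 ± 0.161 to 141 ± 18.8 CPM, and the gap junction gene Gjb2 fell from 296 ± 27.0 to 27.9 ± 2.91 CPM (log2 fold change -3.41 ± 0.10). Ppp2r2c, a regulatory subunit of protein phosphatase 2A, had 1 and 3 counts in the control libraries and 1293 and 1318 counts in the treated ones, which put it at 42.0 ± 1.12 CPM. Fzd10, Mgam, Fam159b, Nppc, Plek2 and Fam180a also had at most 8 counts in any WT control library and rose to between 8.86 and 20.2 CPM. Among the other genes with the largest falls were the transcription factor genes Nrf1 (log2 fold change -3.03 ± 0.13) and Tfap4 (-2.75 ± 0.12), Snhg4 (-2.75 ± 0.10), Rgs4 (-2.60 ± 0.12), Enpp4 (-2.56 ± 0.18), Fam84b (-2.53 ± 0.08) and Snx24 (-2.42 ± 0.14).

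Of the 48 measured p53-activated genes, 46 rose in WT cells and 2 were not called, or 47 rose adjusted over the list alone, with a median log2 fold change of 2.03. Pmaip1 (4.21 ± 0.08), Perp (4.27 ± 0.10) and Trp53inp1 (3.74 ± 0.08) were among them. Of 22 p53 apoptosis genes, 18 rose, 2 fell and 2 were not called (19 rose and 2 fell adjusted over the list alone), and Eda2r rose by a log2 fold change of 2.89 ± 0.08. Of 44 G2/M and mitosis genes, 38 fell, 3 rose and 3 were not called, counts that were the same adjusted over the list alone. Mki67, the proliferation marker, had a log2 fold change of -1.79 ± 0.08, the spindle genes Tpx2 and Prc1 had -1.54 ± 0.08 and -1.23 ± 0.07, and the kinetochore gene Spc25 rose by 1.27 ± 0.07. Of 39 G1/S and DNA replication genes, 27 fell, 2 rose and 10 were not called (28 fell and 2 rose adjusted over the list alone), with Uhrf1 at -1.83 ± 0.08 and the licensing factor gene Cdt1 at -1.79 ± 0.15. Of 29 genes of homologous recombination and Fanconi anemia repair, 17 fell, 4 rose and 8 were not called, the same counts as adjusted over the list alone. Brca2 fell (-1.73 ± 0.16).

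Of 25 genes of the ATF4 integrated stress response, 17 fell, 1 rose and 7 were not called (18 fell and 1 rose adjusted over the list alone), with Atf4 at a log2 fold change of -1.11 ± 0.08 and Mthfd2 at -1.64 ± 0.09. Of 24 cholesterol biosynthesis genes, 12 fell, 3 rose and 9 were not called, the same adjusted over the list alone, with Insig1 at -1.76 ± 0.08 and Hsd17b7 at 0.84 ± 0.07. Of 35 Hox and limb or trunk patterning genes, 15 fell, 5 rose and 15 were not called, the same adjusted over the list alone, with Hoxd13 at -1.33 ± 0.08 and Hoxc8 at -1.25 ± 0.10. Of 22 NRF2 antioxidant genes, 13 rose, 1 fell and 8 were not called, the same adjusted over the list alone, with Srxn1 at 1.52 ± 0.09 and Gclc at 1.25 ± 0.08. Of 15 smooth muscle and myofibroblast genes, 8 fell, 1 rose and 6 were not called, the same adjusted over the list alone, with Mylk at -1.44 ± 0.08 and Cnn2 at -0.77 ± 0.08.

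In all, 7037 genes passed edgeR's quasi-likelihood test in WT cells, 3589 higher and 3448 lower, of which 1630 rose and 921 fell at least 2-fold. In camera's list test, the p53-activated list (adjusted p = 1.43e-54) and the p53 apoptosis list (3.52e-23) stayed called with an estimated correlation (adjusted p = 0.0102 for each). The calls of 8 further lists were lost with it. Their camera adjusted p was 4.63e-14 for G2/M, 8.15e-05 for G1/S, 0.0341 for homologous recombination, 0.00202 for ATF4, 0.0192 for cholesterol, 0.0189 for Hox, 0.0464 for NRF2 and 0.0464 for smooth muscle. With an estimated correlation the adjusted p was 0.0892 for G2/M, 0.160 for G1/S, 0.161 for homologous recombination, 0.106 for ATF4, 0.160 for cholesterol, 0.337 for Hox, 0.390 for NRF2 and 0.515 for smooth muscle. Without WT doxorubicin library B the adjusted p was 0.0656 for homologous recombination and 0.0561 for Hox. The NRF2 and smooth muscle calls were each lost in 5 of the 8 fits that left out 1 library: NRF2 without WT control A, WT doxorubicin B, mutant control A or B, or mutant doxorubicin B (adjusted p between 0.0504 and 0.0703), and smooth muscle without WT control B, WT doxorubicin A, mutant control A or B, or mutant doxorubicin B (0.0504 to 0.0876).

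**Figure D1:**
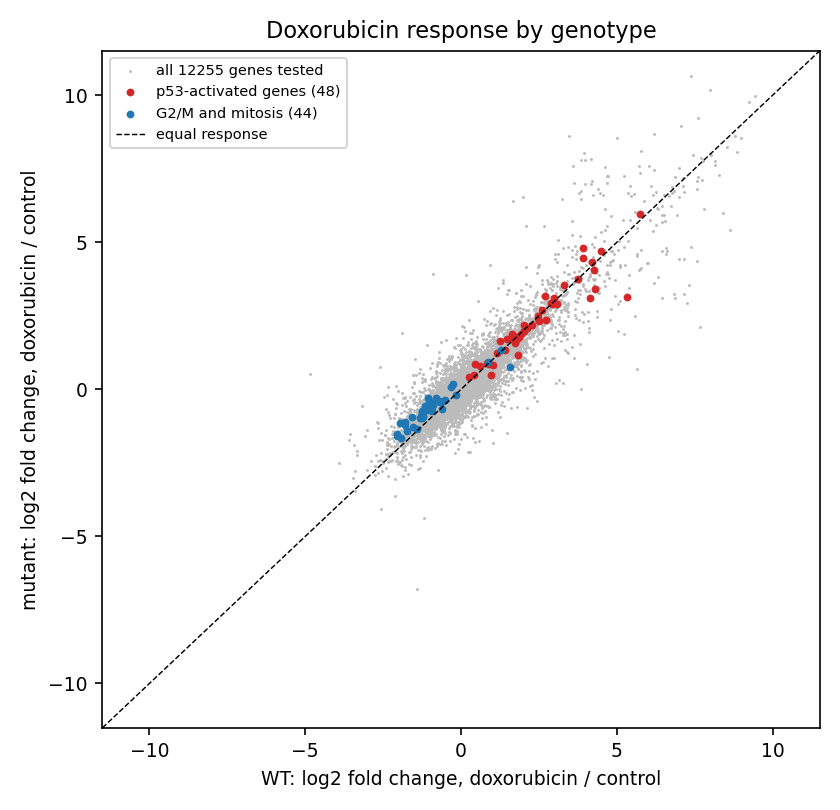
Each point is 1 of the 12255 tested genes, with its log2 fold change with doxorubicin in WT cells on the x axis and in mutant cells on the y axis (n = 2 libraries per group, p53-activated and G2/M genes in color, dashed line at equal responses). Pearson's r across genes was 0.908.

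Other fixed lists held genes that changed in WT cells but were not called by camera, which compares a list with all other genes. Of 25 NF-kappaB and inflammatory genes 10 rose and 8 fell (11 and 8 adjusted over the list alone), and the chemokine gene Ccl2 rose by a log2 fold change of 2.28 ± 0.10 (list adjusted p = 0.0816). Of 26 interferon-stimulated genes 14 rose and 1 fell, the same adjusted over the list alone, with a median of 0.72 and 24 of the 26 above 0 (list adjusted p = 0.121, or adjusted p = 0.00662 with no filter and 0.000463 without WT control library B). The NF-kappaB list was called without WT doxorubicin library B (adjusted p = 0.0476). Of 21 immediate early genes 9 rose and 9 fell (9 and 10 adjusted over the list alone), with Fos at 2.75 ± 0.11 and Myc at -1.88 ± 0.12. The immediate early list had an adjusted p of 0.968, a median below 0 (-0.16) and a mean above 0 (0.13). Only 7 of the 35 listed replication-dependent histone genes had enough counts to be tested. Of these 4 rose and 1 fell, the same adjusted over the list alone, with Hist2h3c1 at 1.47 ± 0.09 and Hist1h1c at -1.36 ± 0.11 (list median 1.31, adjusted p = 0.348). Of 20 endoplasmic reticulum chaperone genes 5 rose and 9 fell (adjusted p = 0.573), of 30 extracellular matrix and fibroblast genes 7 rose and 11 fell (0.183), both the same adjusted over the list alone, and of 45 ribosomal protein genes 4 rose and 8 fell, or 3 and 4 adjusted over the list alone (0.393). With fry, which asks whether the genes of a list move one way on balance and compares them with no other genes, the NF-kappaB (adjusted p = 0.000911), histone (0.00884), chaperone (0.0226) and extracellular matrix (0.0263) lists were called.

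Among markers of other cell types, 7 of 13 macrophage and leukocyte markers rose with doxorubicin in WT cells and none fell (list adjusted p = 0.350), 1 of 4 endothelial markers rose (0.650), and 3 of 4 epithelial markers rose (0.232). Of 6 skeletal muscle markers 1 rose and 1 fell (0.968), of 6 neural markers 3 rose and 3 fell (0.968), and of 6 cartilage and bone markers 2 rose and 2 fell (0.573). For these 6 lists the counts were the same adjusted over the list alone. Of the 5 sex-linked genes 3 fell (0.50, 3 adjusted over the list alone). Of the 12 genes in the list near Cdkn1a, 2 rose, Cdkn1a itself among them, and 3 fell (0.968, 2 and 2 adjusted over the list alone). Fry called the macrophage (adjusted p = 0.000911), epithelial (0.00117), cartilage and bone (0.0226) and sex-linked (0.0342) lists. The erythroid list had too few genes to be tested. No mitochondrially encoded gene was in the table under a name of that list.

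The next comparison asked the same of mutant cells. Mdm2 rose from 140 ± 6.53 to 1051 ± 20.9 CPM (log2 fold change 2.91 ± 0.07) and Cdkn1a from 8.98 ± 0.526 to 50.8 ± 1.28 CPM (2.50 ± 0.10), while Trp53, at 8.11 ± 0.509 and 8.09 ± 1.20 CPM, did not pass. Rai2 (7.23 ± 0.19), Vnn1, which encodes pantetheinase (6.04 ± 0.19), and Magel2 (5.74 ± 0.19) rose. Ppp2r2c, Fzd10, Slc4a11, Plek2 and Fam159b rose from at most 3 counts per control library to between 9.32 and 33.5 CPM. The largest falls were those of Gjb2 (-3.47 ± 0.10), Nrf1 (-2.75 ± 0.13), Snx24 (-2.68 ± 0.15), Tfap4 (-2.62 ± 0.12), Snhg4 (-2.62 ± 0.10), Pcdh11x (-2.48 ± 0.28), the sulfotransferase gene Chst2 (-2.47 ± 0.09) and Fam84b (-2.45 ± 0.08).

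Of the 48 p53-activated genes, 47 rose in mutant cells and 1 was not called (48 rose adjusted over the list alone), with a median log2 fold change of 2.03, and Pmaip1 rose by 4.34 ± 0.08 and Zfp365 by 3.53 ± 0.08. Of the 22 p53 apoptosis genes 19 rose and 2 fell, the same adjusted over the list alone, with Perp at 4.05 ± 0.10 and Eda2r at 2.92 ± 0.08. Of the 44 G2/M genes 37 fell, 3 rose and 4 were not called (38 fell and 3 rose adjusted over the list alone). Mki67 was at -1.13 ± 0.08, Tpx2 at -1.27 ± 0.08, and Cenpf, which encodes a centromere protein, at -1.51 ± 0.11. Of the 39 G1/S genes 21 fell and 4 rose, the same adjusted over the list alone, with Uhrf1 at -1.55 ± 0.08 and Rrm2, which encodes a subunit of ribonucleotide reductase, at 0.65 ± 0.06. The ATF4 list (16 fell, 1 rose), the cholesterol list (13 fell, 2 rose), the NRF2 list (12 rose, 2 fell) and the smooth muscle list (8 fell, 1 rose) had the same counts adjusted over the list alone. In the Hox list 16 genes fell and 4 rose (17 and 4 adjusted over the list alone), and of 29 homologous recombination genes 11 fell and 4 rose, the same adjusted over the list alone.

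In mutant cells 6646 genes passed edgeR's test, 3469 higher and 3177 lower, of which 1564 rose and 797 fell at least 2-fold. The p53-activated list (camera adjusted p = 4.96e-58, or adjusted p = 0.00336 with an estimated correlation) and the p53 apoptosis list (6.24e-26, or adjusted p = 0.00506 with an estimated correlation) were called with both. The calls of G2/M (4.46e-07), G1/S (0.00440), ATF4 (0.00117), cholesterol (0.00440), Hox (0.0142), NRF2 (0.0409) and smooth muscle (0.0294) were lost with an estimated correlation, where the adjusted p was 0.110, 0.297, 0.110, 0.110, 0.372, 0.372 and 0.505 in the same order. The homologous recombination list was not called (0.230), but was with no filter (0.0138) and with fry (0.000959). Fry also called the chaperone (0.00456), epithelial (0.00456), extracellular matrix (0.0233), macrophage (0.00122), NF-kappaB (0.00137) and histone (0.0106) lists. The NRF2 call was lost without mutant control library A or mutant doxorubicin library B (adjusted p = 0.0623 and 0.0988).

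The responses of both genotypes fell largely on the same genes. Of the genes called in WT and in mutant cells, 3038 rose in both and 2806 fell in both, where 1016 and 894 would be shared if the calls were independent, and 2 genes changed in opposite directions. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.908 and the slope of the mutant on the WT response was 0.897. Noise in the WT response lowers such a slope, so its value alone does not show a weaker response in mutant cells. With the genotypes averaged, 8132 genes were called, 4133 higher and 3999 lower, and 48 of 48 p53-activated genes rose. Among the 4133 genes higher on average, the median of the mutant minus the WT log2 response was -0.02 (camera p = 0.0279, or p = 0.212 with an estimated correlation). Among the 3999 genes lower on average it was 0.04 (p = 0.00837, or p = 0.172 with an estimated correlation), and it was -0.00137 without mutant doxorubicin library A (p = 0.480). The up-regulated set also missed camera's threshold without WT doxorubicin A (median -0.0126), mutant control A (-0.0165) or B (-0.00563), or mutant doxorubicin A (-0.0100), and the down-regulated set without WT doxorubicin A (0.0141) or mutant control B (0.0219).

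The study's title names the question of which part of the response depends on Dino. The difference between the responses compares the genotypes, whose libraries also differed in sex-linked expression. The level of Dino was not analysed, so this comparison cannot tell an effect of Dino from other differences between the cultures. Genes of G2/M and mitosis fell less with doxorubicin in mutant cells than in WT cells, with a median difference of 0.37 on the log2 scale over 44 genes. Mki67 fell from 119 ± 4.92 to 34.4 ± 2.31 CPM in WT cells and from 116 ± 3.05 to 53.2 ± 1.48 CPM in mutant cells (difference 0.67 ± 0.11). Hmmr, which encodes a spindle-associated hyaluronan receptor, went from 47.1 ± 2.49 to 22.8 ± 0.635 CPM and from 46.7 ± 0.829 to 38.1 ± 3.47 CPM (difference 0.76 ± 0.12). Esco2, a cohesin acetyltransferase gene outside that list, rose more in mutant cells, from 44.6 ± 0.0931 to 88.3 ± 3.74 CPM, than in WT cells, from 41.2 ± 3.90 to 50.8 ± 6.54 CPM (difference 0.68 ± 0.13). The difference was below 0 for Pttg1, which encodes securin (-0.81 ± 0.14), for the transcription factor genes Bcl11b (-0.62 ± 0.11) and Bnc1 (-0.98 ± 0.18), and for Apobec1, a cytidine deaminase gene (-1.45 ± 0.24). These 4 genes were higher in mutant than in WT control libraries, with Bcl11b at 197 ± 0.173 against 93.8 ± 11.2 CPM and Pttg1 at 18.4 ± 0.613 against 9.31 ± 0.866 CPM.

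Of the 44 G2/M genes, the difference passed the test upward for 2 and downward for 1 (21 and 1 adjusted over the list alone), and it was above 0 for 41. Of 39 G1/S genes and 29 homologous recombination genes none was called, with or without adjustment over the list alone, and the medians were 0.21 and 0.20. Mcm6, a helicase subunit gene, had a difference of 0.50 ± 0.15 and Brca2 one of 0.66 ± 0.23, neither past the test. None of the 48 p53-activated genes was called, and their median difference was -0.01. Cdkn1a had a difference of 0.05 ± 0.14, Mdm2 of -0.18 ± 0.10 and Trp53 of 0.20 ± 0.20.

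**Figure D2:**
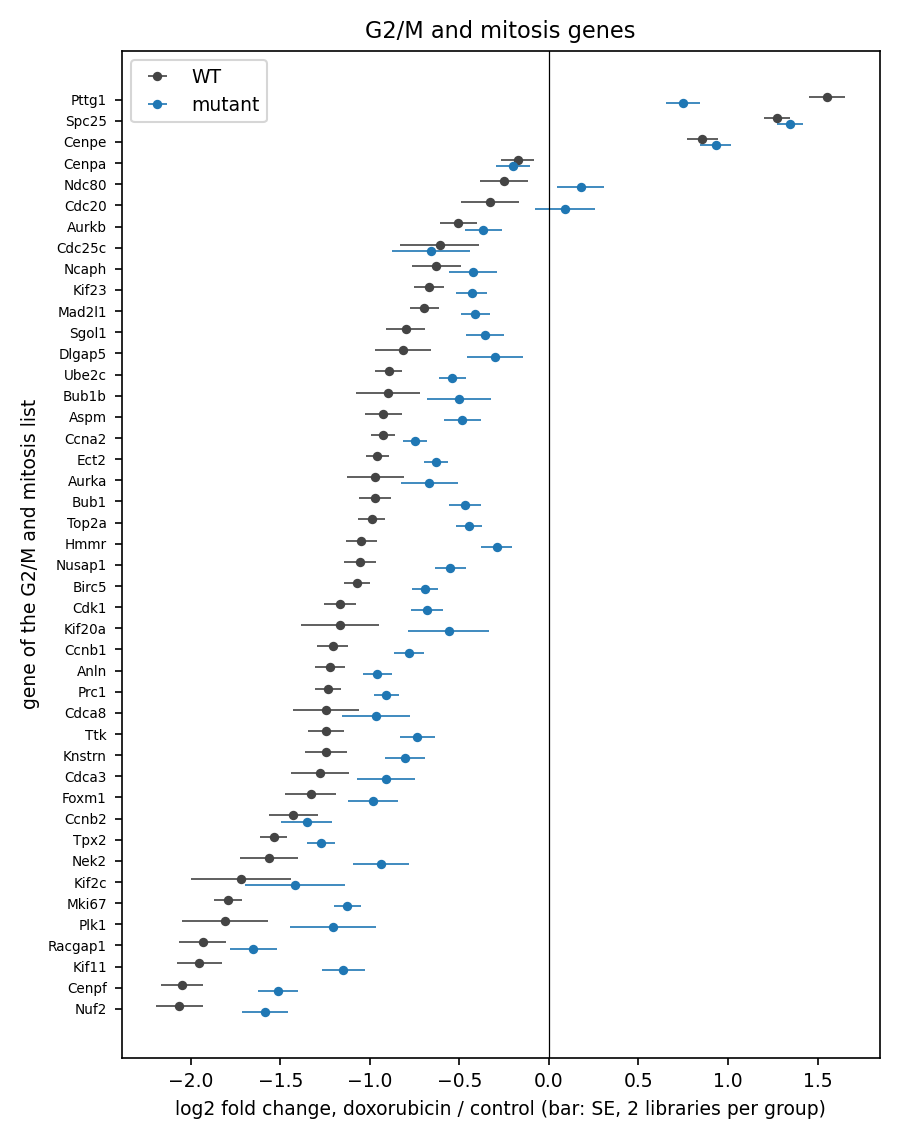
The log2 fold change with doxorubicin of each of the 44 G2/M and mitosis genes in WT and in mutant cells (points, with bars of 1 SE, n = 2 libraries per group). The median was -1.05 in WT and -0.66 in mutant cells.

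In this test of the difference 9 genes passed edgeR's threshold, 4 upward and 5 downward, and 697 had an unadjusted p under 0.05, where 613 would with no change in any gene. Adjusted p-values were 0.019 for Mki67, Hmmr and Apobec1, 0.028 for Pttg1, 0.032 for Bcl11b, and 0.042 for Esco2 and Bnc1. The remaining pair, Prdm16 (1.74) and Pcdhb3 (-2.40), had low counts and were chosen after their values were seen. In camera's test the G2/M list had an adjusted p of 4.06e-27, or adjusted p = 0.0479 with an estimated correlation. The G1/S list had 2.18e-05 and the homologous recombination list 0.000316, and both calls were lost with an estimated correlation (adjusted p = 0.189 and 0.120), as was that of G1/S with fry (0.138). With all 8 libraries no other list was called. The interferon list was called upward without WT control A (adjusted p = 0.00112) and downward without WT control B (3.51e-07), against 0.772 with both, so its difference rested on single libraries. The ribosomal list was called upward without mutant control B (0.0199, against 0.554). The number of genes called was 0 without WT control B, mutant control A or mutant doxorubicin B, 2 without mutant control B, 3 without WT control A, 4 without mutant doxorubicin A and 60 without WT doxorubicin B, while the G2/M median stayed between 0.34 and 0.41.

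**Figure D3:**
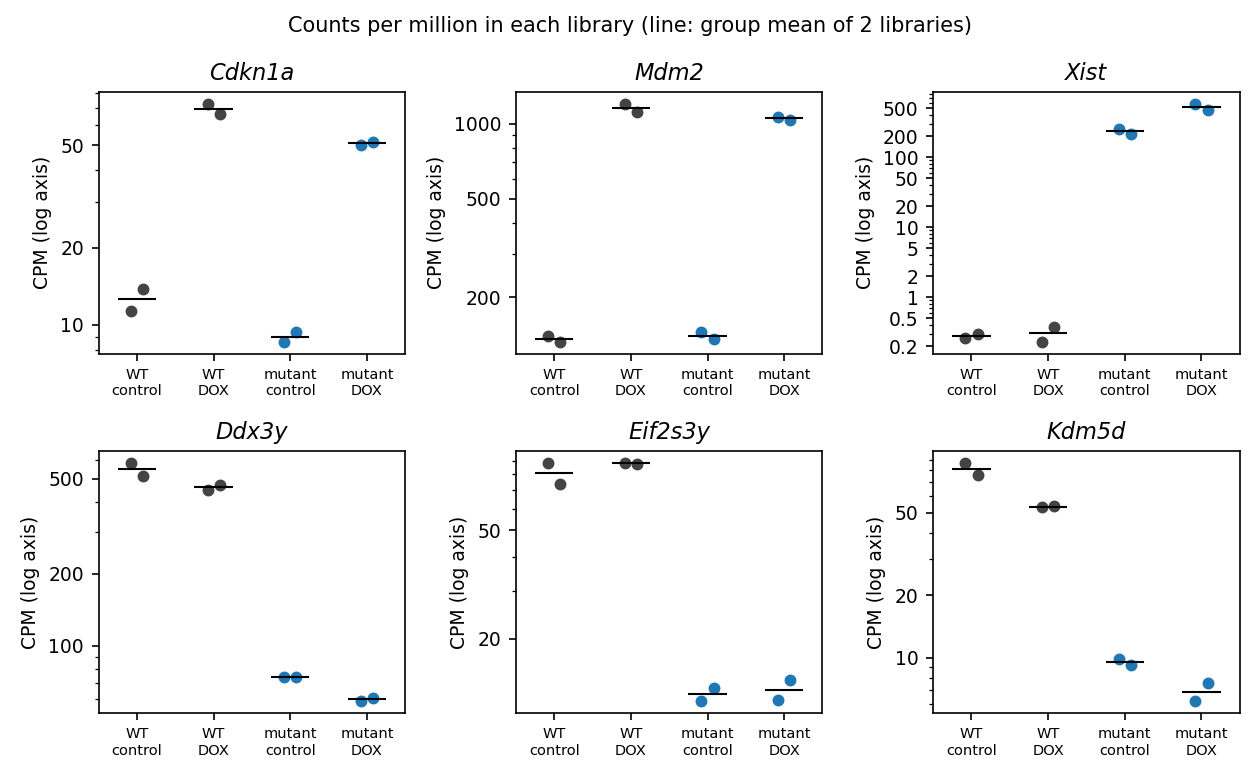
CPM of single genes in each of the 8 libraries on a log axis, with a line at the mean of the 2 libraries of each group. Cdkn1a lay between 8.61 and 13.8 CPM in the control libraries and between 49.9 and 72.5 CPM in the treated ones.

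Without doxorubicin, the genotypes were compared for expression that differs before damage. Cdkn1a was lower in mutant cells, at 8.98 ± 0.526 against 12.6 ± 1.76 CPM (log2 fold change -0.49 ± 0.11, edgeR adjusted p = 0.0083), whereas Mdm2 (0.04 ± 0.07) and Trp53 (-0.04 ± 0.14) did not pass. Cdkn1b, which encodes the cell cycle inhibitor p27, was at 7.72 ± 0.826 CPM in mutant and 68.0 ± 5.12 CPM in WT cells (-3.14 ± 0.13), and the tumor necrosis factor receptor gene Tnfrsf1b was also lower (-2.73 ± 0.18). Shoc2, a scaffold gene of the Ras pathway, was at 187 ± 5.65 against 38.1 ± 0.219 CPM (2.30 ± 0.08). Tnfaip6 (1.90 ± 0.08), Fxyd6 (2.70 ± 0.18), Angptl7 (2.25 ± 0.18), Lin7a (1.93 ± 0.17) and Lgr5, a receptor for R-spondins (1.82 ± 0.14), were higher too. Mgam was also called higher, at 0.375 ± 0.045 against 0.044 ± 0.0623 CPM, from 0 and 3 counts in the WT libraries. Among the sex-linked genes, Xist was at a log2 fold change of 9.69 ± 0.18, Kdm5d at -3.08 ± 0.10, Uty at -2.93 ± 0.12, Ddx3y at -2.88 ± 0.08 and Eif2s3y at -2.69 ± 0.10.

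Of 26 interferon-stimulated genes, 11 were lower in mutant control libraries and 15 were not called (16 lower adjusted over the list alone), with a median of -1.09. Ifi44 (-3.53 ± 0.53), Usp18 (-3.13 ± 0.53) and Rtp4 (-2.29 ± 0.34) were among them. Their levels in WT control A and B lay far apart, at 2.64 and 10.1 CPM for Ifi44, 1.26 and 5.37 for Usp18, and 3.27 and 8.98 for Rtp4. The summed CPM of the list was 85.3 in WT control A, 139 in WT control B, 63.7 in mutant control A and 60.4 in mutant control B, and the median was -0.49 without WT control B. Of 13 macrophage and leukocyte markers 2 were higher, Cd53 (0.46 ± 0.09) and Ptprc (0.67 ± 0.18), and none lower (6 higher adjusted over the list alone). Of 6 neural markers 2 were higher, Gap43 (0.82 ± 0.11) and Sox2 (1.16 ± 0.27), or 4 adjusted over the list alone. Among p53-activated genes 3 were higher and 3 lower (3 and 4 adjusted over the list alone), the lower ones being Cdkn1a, Pmaip1 (-0.57 ± 0.07) and Perp (-0.73 ± 0.11). The p53-activated list had an adjusted p of 0.777, a median of 0.02 and a mean of -0.02.

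EdgeR's test called 726 genes in this comparison, 337 higher and 389 lower in mutant cells, of which 84 and 108 differed at least 2-fold. In camera's test the adjusted p was 5.60e-42 for the sex-linked list (adjusted p = 0.0167 with an estimated correlation), 1.93e-12 for interferon, 0.00241 for neural and 0.00423 for macrophage markers. The last 3 calls were lost with an estimated correlation (adjusted p = 0.474, 0.190 and 0.190), and that of interferon also with fry (0.140). No other list was called in this fit, but the calls of 3 lists depended on the setting. The G2/M list (adjusted p = 0.209) was called higher in mutant cells with no filter (0.0269) and without WT control B (0.0273). The ribosomal list (0.209) was called higher with no filter (0.00978) and without mutant control A (0.00571). The cartilage and bone list (0.0724) was called lower with fry (0.0274) and without WT control B (0.0154). In the sex-linked list 1 gene was higher and 4 were lower, also adjusted over the list alone. The number of genes called was 388 without WT control B, 405 without mutant control A and 408 without mutant control B.

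With doxorubicin, the genotypes were compared in damaged cells. Cdkn1a was again lower in mutant cells, at 50.8 ± 1.28 against 69.3 ± 4.48 CPM (log2 fold change -0.45 ± 0.09, edgeR adjusted p = 0.0023), as were Perp (-0.95 ± 0.08) and Pmaip1 (-0.44 ± 0.07), while Mdm2 (-0.14 ± 0.07) and Trp53 (0.16 ± 0.14) did not pass. Cdkn1b (-3.02 ± 0.16), Tnfrsf1b (-2.73 ± 0.18), Usp18 (-3.28 ± 0.28) and Ifi44 (-3.84 ± 0.49) were lower. Shoc2 (2.20 ± 0.08), Tnfaip6 (2.25 ± 0.08), Fxyd6 (2.89 ± 0.17), Angptl7 (2.25 ± 0.22), Lgr5 (1.84 ± 0.21), Apold1 (2.90 ± 0.19) and Cap1, an actin-binding protein gene (1.97 ± 0.12), were higher. Xist had a log2 fold change of 10.72 ± 0.18, Kdm5d of -2.96 ± 0.11, Ddx3y of -2.95 ± 0.08, Uty of -2.85 ± 0.12 and Eif2s3y of -2.75 ± 0.10.

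Of the 44 G2/M genes 25 were higher in treated mutant than in treated WT cells and 19 were not called (30 higher adjusted over the list alone), with Top2a at 97.0 ± 0.892 against 59.6 ± 4.33 CPM (0.70 ± 0.08) and the kinase gene Ttk at 0.78 ± 0.11. In the control libraries 1 of these 44 genes, Pttg1, was called (0.98 ± 0.10). Of 39 G1/S genes 3 were higher with doxorubicin, the same adjusted over the list alone, with Mcm6 at 0.88 ± 0.11. Of 26 interferon-stimulated genes 13 were lower (21 adjusted over the list alone). Of 25 NF-kappaB genes 5 were lower, with Cxcl1 at -0.91 ± 0.12 and Ccl2 at -0.53 ± 0.09 (2 higher and 7 lower adjusted over the list alone). Of 6 neural markers 2 were higher, Gap43 (0.79 ± 0.11) and Elavl4 (0.49 ± 0.11), or 3 adjusted over the list alone. Of 45 ribosomal protein genes 5 were higher and 1 lower (6 and 1 adjusted over the list alone).

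With doxorubicin 949 genes were called, 481 higher and 468 lower in mutant cells, of which 65 and 98 differed at least 2-fold. Of these, 202 were higher and 248 lower both with and without doxorubicin, against 13.2 and 14.9 if the calls were independent. In camera's test the sex-linked list (adjusted p = 5.82e-29) and the G2/M list (6.11e-20) stayed called with an estimated correlation (adjusted p = 0.0197 and 0.0423). The calls of interferon (3.09e-16), G1/S (0.00898), neural (0.00898), NF-kappaB (0.0113) and ribosomal genes (0.0227) were lost with it (adjusted p = 0.241, 0.241, 0.232, 0.232 and 0.531 in that order), and the ribosomal call was also lost without mutant doxorubicin library B (adjusted p = 0.154). With no filter the neural (0.0747) and NF-kappaB (0.0998) calls were lost, and with fry those of interferon (0.0515) and ribosomal genes (0.10). The homologous recombination and macrophage lists (0.0603 each) were called higher with no filter (0.00785 each), with fry (0.00695 and 0.00811) and without WT doxorubicin A (0.0420 each). The smooth muscle list (0.0763) was called lower with no filter (0.0234) and without WT doxorubicin A (0.0135). Fry also called the cholesterol, epithelial and Cdkn1a neighborhood lists lower (0.0264 each). The neighborhood list holds Cdkn1a itself, which was lower. The number of genes called was 537 without WT doxorubicin A, 535 without mutant doxorubicin A and 608 without mutant doxorubicin B.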

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

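All tests of explanations in this part were chosen after the results were seen, except the test of reads shared between near-identical copies.

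The test of the difference between the responses singled out 3 gene lists and 9 genes. The median difference, mutant minus WT on the log2 scale, was 0.37 for G2/M and mitosis, 0.21 for G1/S and DNA replication, and 0.20 for homologous recombination and Fanconi anemia repair. The last 2 calls were lost with an estimated correlation (adjusted p = 0.189 and 0.120), and that of G1/S also with fry (0.138). Single genes that passed it were Mki67 (0.67), Hmmr (0.76), Esco2 (0.68), Prdm16 (1.74), Apobec1 (-1.45), Pttg1 (-0.81), Bcl11b (-0.62), Pcdhb3 (-2.40) and Bnc1 (-0.98). None of the 9 passed in edgeR without WT control B, mutant control A or mutant doxorubicin B. With all 8 libraries 697 genes had an unadjusted p under 0.05, where 613 would with no change in any gene, and DESeq2 called 13 genes and limma-voom 4.

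As a list, G2/M genes fell less with doxorubicin in the mutant libraries, with a difference above 0 for most but not all members. Its member Pttg1 rose in both genotypes, and less in mutant cells. For the list, the tables argue against 3 technical explanations. Scaling would move all genes alike, but the list's median difference lay 0.36 above the median of all genes, and no single library carried it, since the lowest median with 1 library left out was 0.34. A doxorubicin effect weaker in all genes alike by the share seen in the G2/M list would have put the median difference of the p53-activated list at -0.72, and it was -0.00841. The sex or embryo of origin of the cultures stays open and cannot be told apart from the genotype, because Xist was above every WT library in 4 of 4 mutant libraries. An effect of the Dino genotype itself was not separated from it.

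Xist was present and Y-linked genes were at 11.8% to 15.5% of their WT level in the same mutant libraries. Reads of X-linked copies counted on the Y-linked genes are argued against, since in 3 of 4 pairs the Y-linked gene responded to doxorubicin unlike its X-linked copy by over 2 SE. A mixture of XX and XY cells may fit, because the shares of the 4 Y-linked genes in both treatments differed by at most 1.31-fold, as they would if 1 fraction of XY cells set them all. RNA or reads carried over from WT libraries would leave every other gene at no less than the Y-linked share of its WT level. Among genes at 10 CPM or more in WT, 0 lay below that share by over 2 SE in both treatments. Carry-over thus cannot be told apart from such a mixture.

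Genes called between the genotypes were crowded on chromosome 4, with 65 called against 44.2 expected without doxorubicin (Fisher's exact test, adjusted p = 0.00890) and 94 against 57.1 with it (2.24e-05), as they were on chromosome 9 (57 against 40.3, adjusted p = 0.0305, and 78 against 52.0, 0.00133) and, with doxorubicin, on chromosome 1 (84 against 55.7, 0.000878). With the number called on chromosome 4 kept, its fullest window of 50 neighboring genes, from Prdm2 to Per3, held 14, where the 95th percentile of 10000 shuffles within the chromosome was 12, so a strain or donor haplotype that differs between the genotypes stays open, along with any other cause that acts on neighboring genes. Reads shared between near-identical copies stay open. Without Gm, Rik and Zfp names the fullest window on chromosome 4 held 10, and the 95th percentile of shuffles over all autosomes was 12. That sets a window of a single chromosome against the fullest window of all autosomes, so this test cannot decide the question. Crowding was not confined to this chromosome, as chromosome 6 also had a window of 14 and chromosomes 10 and 16 had windows of 13, and without those names chromosomes 2, 6, 10, 13 and 16 had windows of 13 or 14. Other chromosomes held fewer called genes than expected in Fisher's test. Chromosome 11 had 30 against 55.8 without doxorubicin (adjusted p = 0.000655) and 45 against 72.0 with it (0.00139). Chromosome 17 had 12 against 31.4 (0.000655) and 29 against 40.5 (0.114), and its fullest window held 3. Chromosome 8 had 25 against 36.6 (0.131) and 26 against 47.3 (0.00204).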

How the results depend on the processing

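Tests without genes of chromosomes X and Y were chosen after seeing the data; the others were planned. For the WT, mutant and average responses and their overlap, the number of genes called stayed within 1.5-fold under every alternative run. Which direction held more calls turned with the scaling. With upper-quartile factors 3318 genes were higher and 3764 lower in WT cells, 3160 and 3505 in mutant cells, and 3807 and 4349 on average. The difference between the responses called 9 genes and varied more: 4 with limma-voom, 48 with no filter, 5 with the stricter filter, 14 with a term for the library letter, 0 with that term within each genotype, 18 at an adjusted p of 0.10 (more by construction), 10, 9 and 13 with DESeq2 size factors, upper-quartile factors and DESeq2, 11 without chromosomes X and Y, and 0 to 60 with 1 library left out (0 without WT control B, mutant control A or mutant doxorubicin B, 2 without mutant control B, 3 without WT control A, 4 without mutant doxorubicin A, 60 without WT doxorubicin B); the cause was not tested. With all 8 libraries 697 genes had an unadjusted p under 0.05 in edgeR, against 613 with no change in any gene. Mutant against WT without doxorubicin called 726 genes, and 388 to 858 with 1 library left out (388 without WT control B, 405 and 408 without mutant control A and B). With doxorubicin it called 949, and 535 to 1229 (535 and 608 without mutant doxorubicin A and B, 537 without WT doxorubicin A), where the lone library was assumed to vary like the others and the cause was not tested. Without chromosomes X and Y these counts were 696 and 907. With an estimated correlation 2, 2, 1, 1 and 2 lists were called in place of 10, 9, 3, 4 and 7. The order is the WT response, the mutant response, the difference, and mutant against WT without and with doxorubicin. In the WT response the estimate was -0.0212 for ATF4, -0.0280 for cholesterol and -0.0161 for homologous recombination, below the preset 0.01. A higher correlation among members thus does not account for the loss of these calls. For the other lists that lost their call there the estimate was above 0.01. What else this setting changes was not tested. With fry, which compares a list with no other genes, 18 and 16 lists were called in the WT and mutant responses. The median difference of the up-regulated genes was -0.0190, missed the threshold with an estimated correlation (p = 0.212) and with no filter (-0.0369, p = 0.0501), and ran from -0.0451 to -0.00563 with 1 library left out. That of the down-regulated genes was 0.0359, missed it with an estimated correlation (p = 0.172), and ran from -0.00137 (without mutant doxorubicin A) to 0.0679; the cause was not tested. No called gene that is named changed direction. Uncalled ones did: Trp53 in the mutant response (0.0131 with the stricter filter; -0.16 to 0.14 with 1 library left out), in mutant against WT without doxorubicin (-0.13 to 0.0564) and with it (-0.000973 to 0.30); in the difference Cdkn1a (-0.11 to 0.18), Tnnt2 (-0.83 to 0.14), Kdm5d (-0.0224 to 0.25), Ddx3y (-0.155 to 0.0241), Eif2s3y (-0.188 to 0.0597) and Uty (-0.0410 to 0.21); and without doxorubicin Mdm2 (-0.00129 to 0.0867). A term for sex could not be fitted, since Xist splits the libraries exactly as the genotype does. In counts simulated with 2 libraries per group, the test of the difference called 24.6% to 26.2% of changes of log2 0.5 and 55.2% to 74.6% of changes of log2 1. It also called 7 unchanged genes in each of 3 simulations (5.34% to 6.36% of its calls). At this depth and number of libraries smaller differences were thus often missed. These simulations called 110 to 131 genes in the difference, against 9 in the real data, so the shares may not hold there.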

Other observations

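The splits of libraries were planned; the gene families, Actb, Srsf3, the X-linked genes and the test of gene length were chosen after their values were seen.

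Of 8 small nucleolar RNA host genes, whose introns hold guide RNAs for ribosome assembly, 7 fell with doxorubicin and none rose in WT cells (median log2 fold change -0.84) and in mutant cells (median -0.70), with the same counts under 3 scalings. Of all 12255 genes tested, 3448 fell in WT and 3177 in mutant cells. The group was not tested as a set, and none was called in the difference between the responses (smallest adjusted p = 0.969). Srsf3, which encodes a splicing factor and lies next to Cdkn1a, fell by 1.18 and 1.17 on the log2 scale in WT and mutant cells, in the direction opposite to its neighbor.

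Actb, often used as a reference gene, was not stable in these libraries. It was at 37768 ± 51.2 CPM in WT control and 25429 ± 2698 CPM in WT doxorubicin libraries, and at 59376 ± 2652 and 43689 ± 659 CPM in mutant ones (n = 2 each). It fell in both genotypes (log2 fold change -0.57 and -0.44) and was higher in mutant than in WT cells without (0.65) and with doxorubicin (0.78), under all 3 scalings. Gapdh stood at 0.404 to 0.784 CPM as group means, and whether its reads were lost or assigned elsewhere in counting was not tested. The name with the most counts in every library was the identifier uc009vev.1, with 5.77% to 9.41% of the counts. Xist, called in the mutant response only, rose there by a log2 fold change of 1.16 ± 0.09, and the difference of the responses was not called (1.03 ± 0.56). X-linked partners of the Y-linked genes were higher in mutant than in WT control libraries: Kdm6a by 0.68, Kdm5c by 0.64, Eif2s3x by 0.60 and Ddx3x by 0.29 on the log2 scale.

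Other ways to split the libraries were weighed for the average doxorubicin response. Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many called genes as the real one, which was the real split itself, with 7457 genes in a model of 2 groups. The highest of the other splits was WT against mutant with 73 genes. Every other split puts treated and control libraries on the same side, so the treatment response adds to its spread and lowers its calls. With 1 of only 35 splits the test cannot exclude chance. The labels also do not say that the 8 libraries are independent.

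A hypothesis was that longer genes fell more with doxorubicin. Across 11847 genes with a length in GRCm38, Spearman's rho of length with the average log2 response was -0.0571, and the median response of the 1185 longest genes was -0.17. Gene length may thus explain at most a small part of the response, and genes are not independent replicates.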
